A study of Mus musculus with 719 samples.

How the data were processed

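Single direction-selective ganglion cells of the mouse retina were profiled one by one with Smart-seq2, a full-length polyA RNA-seq protocol without molecular identifiers. Per the labels' protocols, retinas were dissociated with papain, stained with an antibody against CD11b to mark microglia and with propidium iodide to mark dead cells, and sorted as single cells that carried fluorescent cholera toxin B and were CD11b negative, with or without GFP. Libraries were sequenced as 75 bp paired-end reads on an Illumina NextSeq 500, per the labels' protocols. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.3.1, Cufflinks 2.2.1, Cuffnorm and R 3.5.1 were used with the builds GRCm38.p6 and mm10. The counting of fragments by strand is not given in the sources used here.

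The main table holds a signal per gene and cell that the authors made with Cuffnorm: an estimated fragment count divided by 1 size factor per cell. Size factors ran from 0.133 to 2.776, per the file headers of the deposited table of cells. After multiplication by the size factor, 96.2% of the values above 0 lay within 0.05 of a whole number. The remaining values were not whole, as they would be where Cuffnorm divided fragments between genes, and the reason was not tested. Whole reads were therefore not recovered for the table as a whole and no count model was fitted. The plan named a count model in case raw counts could be had, and the log-scale test that it named for all other units was used. The authors' deposited FPKM table, which divides by gene length and depth, served as an alternative. A table of mapped fragment mass per cell was used for depth, of which the gene table held 90.2% to 96.2% per cell. The tables per transcript were not used here. The number of columns left without a sample was 0.

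A gene's value in a cell was divided by the sum over named genes and scaled to CPM. Within 1 cell the size factor cancels in this step. The table listed 53374 genes, of which 50599 identifiers were matched to GENCODE M21 and 31717 lay at identical coordinates. Coordinates given below are those of GENCODE M21 on GRCm38. Where a symbol occurred more than once, its most abundant row kept the symbol, and the other rows, 101 in all, carried their identifier as well. Each cell had at least 1000 detected genes, the minimum set, where a gene counted as detected at 0.5 fragments or more. No cell was removed. No doublet caller was run, since each library was 1 sorted cell. Single-cell totals ran from 108799 to 1884350 estimated fragments, with a median of 926837. Without molecular identifiers, intervals and upper limits on shares of cells are exact binomial (Clopper-Pearson, 95%) or 3 counts of the total, and cover counting error only. A share of cells with a fragment also depends on depth.

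Each deposited sample is 1 cell and no animal is named. Cells are not replicates, so all cells of 1 group at 1 age were combined into 1 pool, with the mean CPM over cells as its value and each cell weighted equally. The labels gave 19 pools. Ages served as the independent units, since animals of different ages cannot be the same. P-values therefore measure the spread between ages, which may be partly technical, and cells of the upward and downward groups at 1 age may share animals. Comparisons used limma 3.58.1 with trend and robust empirical Bayes on log2(mean CPM + 5), for genes with a mean of at least 5 CPM over the pools in the fit, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fold on this scale understates the change of genes with low values. The difference between cells labelled up and down was fitted with age as a block over 6 ages. The trend with age in ON cells was fitted to the mean of the up and down log2 values at each age, and that in ON-OFF cells to their own 6 pools. ON-OFF cells were compared with ON cells, and with ON cells labelled down, over the 5 shared ages with age as a block. Product terms with age in days tested whether a difference changed with age. Residual degrees of freedom ran from 3 to 5. The log2 change of a trend is the fitted change from the first to the last age. The Pcdh9-Cre cells form 1 pool at 1 age and were described without a test.

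A set of 36 gene lists was written before the data were examined, covering ganglion cell identity, other retinal and non-neural cell types, quality, and neuronal programmes from axon guidance to ion channels. Of these, 32 were tested with camera in limma, in each comparison with at least 4 measured members, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The direction candidates and gate genes were not tested as sets. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, one way. Camera compares the list with all other genes. None of the 56 calls made at the preset correlation passed with an estimated correlation.

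Genes named in the text follow a rule fixed before the data were examined. For the difference between up and down these are the 12 largest differences in each direction among genes past the threshold with the same sign at all 6 ages. For the age trends and for ON-OFF against ON they are the 10 largest in each direction with at least 20 CPM in the highest pool, and for the remaining comparisons the 5 largest. For each list up to 4 members are given, and for the Pcdh9-Cre pool the 10 highest and 10 lowest against ON cells of the same age, detected in at least 25% of the cells of the higher pool. Numbered gene models and clone names were left out, and some genes that the rule names are not reported here. A list of 7 direction candidates was recalled from the paper on these samples and is not independent evidence of a direction.

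The index numbers of the libraries restart after library 314, so the cells were taken as 2 sequencing runs of 314 and 405 cells. The labels do not name runs. Each pool is divided about evenly between the runs except the Pcdh9-Cre pool, which lies in run 2. Each comparison was therefore repeated within each run, an alternative chosen after the data were seen. Alternatives planned beforehand were other pseudocounts, filters, means, scalings and empirical Bayes settings, the FPKM table, equal numbers of cells per pool, other minimums of detected genes, pools without cells of other types, fits without the age block, and fits without each age in turn. A cell was set aside as another type when its summed CPM over 1 list of another cell type exceeded that over the ganglion cell list, which held for 49 cells.

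The fits were tested on the real cells with shuffled group labels, after the pool means of chosen genes were multiplied by known factors. Such pools lack the spread between animals and so give optimistic values. Of genes changed 4-fold, the fits recovered 93.7% for up against down (11296 genes), 67.2% for the age trend in ON cells (11295 genes), 87.9% for ON-OFF against ON (11436 genes), 81.5% for ON-OFF against ON cells labelled down (11411 genes) and 50% for the age trend in ON-OFF cells (11435 genes). For the product terms the recovery was 18.5% for up against down with age (11300 genes) and 31.2% for type with age (11435 genes). Of genes changed 2-fold, 50.8% were recovered for up against down, 56.7% for ON-OFF against ON and 52.3% against ON cells labelled down. The age trends in ON and ON-OFF cells recovered 24.2% and 14.1%, and the product terms of direction and type 3% and 1.5%. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.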

Results

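Direction-selective ganglion cells report the direction in which an image moves over the retina. The study profiled single cells that prefer upward or downward motion, over the days in which their wiring matures. A total of 719 cells was analysed. ON cells came from the Spig1-GFP line, in which GFP-positive cells are labelled up (206 cells) and GFP-negative cells down (184 cells), at postnatal days 4, 5, 7, 8, 10 and 12. ON-OFF cells labelled down came from the HB9-GFP line (237 cells) at postnatal days 4, 5, 8, 10, 12 and 14. A further 92 ON cells of a Pcdh9-Cre line were taken at postnatal day 10 (P10), and their preferred direction is unknown. These make 19 pools of 18 to 92 cells, with 1 pool per group and age. Median depth per pool ran from 855490 to 1122940 estimated fragments in the 18 pools of GFP lines and was 692382 in the Pcdh9-Cre pool. A median of 8012 genes was detected per cell, from 5738 in the ON-OFF pool at P12 to 9524 in the Pcdh9-Cre pool. The highest correlation between any pair of cells was 0.738 over 14359 genes, and 0 pairs held identical values.

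The genes behind the gates were looked at first, since they check the labels. Fstl4, the gene also called Spig1, had a fragment in 96.4% to 100% of the cells of each pool labelled up and in 15% to 39.1% of those labelled down. Mnx1, the gene also called HB9, was listed at 0 in each ON pool and had a fragment in 55.2% to 88.9% of ON-OFF cells per pool. In total 1 cell labelled up lacked Fstl4 and 39 cells labelled down had it.

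The first comparison asks which transcripts separate ON cells that prefer upward motion from those that prefer downward motion. Fstl4 (ENSMUSG00000036264.9, chromosome 11, 52764634 to 53188538, plus strand), which encodes a secreted follistatin-like protein, had a mean of 282 ± 51.7 CPM in up pools against 8.89 ± 9.09 CPM in down pools (SD, n = 6 ages). Ptprk (ENSMUSG00000019889.10, chromosome 10, 28074820 to 28597397, plus strand), a receptor tyrosine phosphatase, had 149 ± 34.2 against 6.95 ± 8.25 CPM, and Ldb2 (ENSMUSG00000039706.11, chromosome 5, 44472132 to 44799680, minus strand), a cofactor of LIM-domain transcription factors, had 162 ± 35.8 against 20.4 ± 12.9 CPM. In the opposite direction, Fibcd1 (ENSMUSG00000026841.7, chromosome 2, 31813290 to 31846005, minus strand), a membrane receptor for acetylated structures, had 1.02 ± 1.32 CPM in up pools against 245 ± 81.8 CPM in down pools. Cntnap5a, a contactin-associated protein, had 2.97 ± 3.37 against 122 ± 67.3 CPM (ENSMUSG00000070695.4, chromosome 1, 115684756 to 116587323, plus strand). Efnb2 (ENSMUSG00000001300.16, chromosome 8, 8617434 to 8661242, minus strand), the ligand ephrin-B2 that signals to and from Eph receptors, had 3.03 ± 4.52 against 107 ± 32.2 CPM.

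In limma, 191 of 11370 genes passed the threshold, 112 higher in up cells and 79 higher in down cells, and 181 of the 191 had the same sign at all 6 ages. Fstl4 was higher by 4.53 ± 0.26 on the log2 scale (SE, adjusted p = 1.61e-06), Ptprk by 3.85 ± 0.23 (adjusted p = 2.02e-06) and Ldb2 by 2.81 ± 0.18 (adjusted p = 3.02e-06). Other genes named as higher in up cells were Sorcs2 (2.60), Amigo2 (2.52), Pmfbp1 (2.43), Cpne5 (2.12), Shisa9 (1.97), Wls (1.83), Mmp17 (1.82) and Avil (1.82). Fibcd1 differed by −5.33 ± 0.21 (adjusted p = 5.71e-08), Cntnap5a by −3.96 ± 0.22 (adjusted p = 1.45e-06) and Efnb2 by −3.91 ± 0.30 (adjusted p = 1.44e-05). Shisa3 (−2.81), the adhesion phosphatase Ptprm (−2.75), Wdr72 (−2.43), Syndig1 (−2.38), Gfi1 (−2.25), Col10a1 (−2.23), Opcml (−2.17), Zfhx4 (−2.12) and Tph2 (−2.08), which encodes the neuronal enzyme of serotonin synthesis, were also higher in down cells. The 24 largest differences, 12 in each direction, had the same sign within each sequencing run, and 23 passed the threshold in run 1 and 20 in run 2. These genes were picked from the same cells, so agreement within the runs is not independent support, here or in later comparisons. Within the runs alone, 117 and 70 genes passed.

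**Figure D1:**
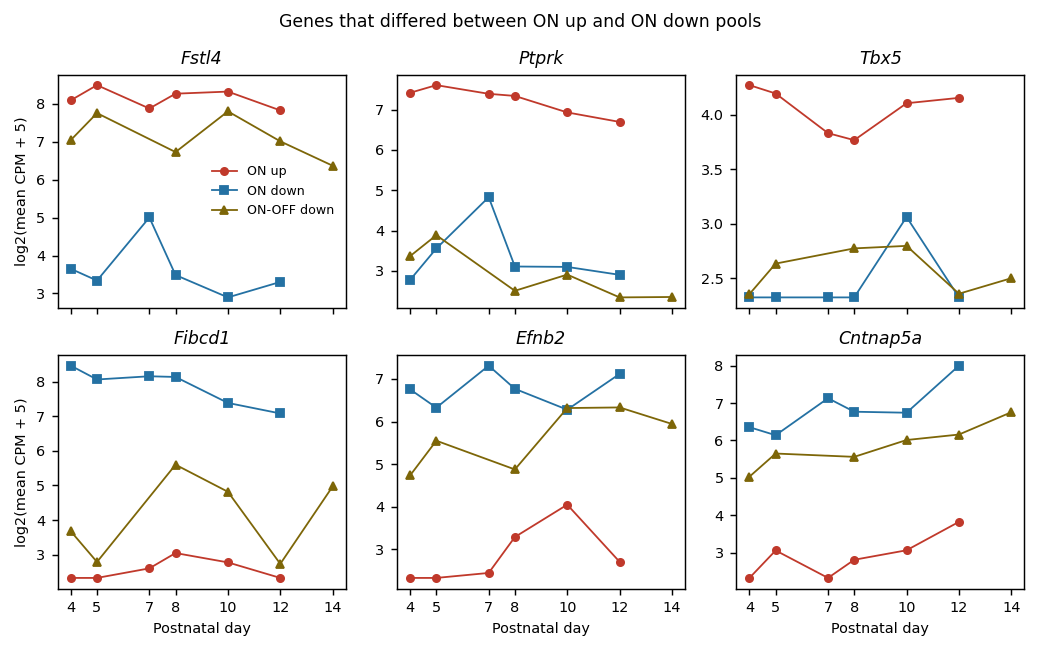
Mean expression of 6 genes, as log2(mean CPM + 5), against postnatal day, with 1 point per pool for ON cells labelled up, ON cells labelled down and ON-OFF cells labelled down. Fstl4 averaged 282 CPM in up pools and 8.89 CPM in down pools, and Fibcd1 1.02 and 245 CPM.

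Among the 7 candidate genes recalled from the paper on these samples, which are not independent evidence, Fstl4, Tbx5 and Sfrp1 were higher in up cells and Fibcd1 in down cells, and the same 3 and 1 passed when adjusted over the list alone. The T-box factor Tbx5 (ENSMUSG00000018263.11, chromosome 5, 119832668 to 119885219, plus strand) had 11.7 ± 2.29 against 0.557 ± 1.37 CPM, a log2 difference of 1.61 ± 0.24 (adjusted p = 0.00364, limma). The Wnt modulator Sfrp1 (ENSMUSG00000031548.7, chromosome 8, 23411502 to 23449632, plus strand) had 42.4 ± 10.6 against 11.6 ± 4.28 CPM (log2 1.53 ± 0.23, adjusted p = 0.00363). Tfap2b (−0.50 ± 0.50, adjusted p = 0.791), Pcdh11x (−1.46 ± 0.62, adjusted p = 0.402) and Calb1 (−0.31 ± 0.17, adjusted p = 0.542) did not pass.

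Receptor genes for GABA and acetylcholine were among those higher in up cells. Of 20 measured genes of GABA and glycine receptors, their anchor and chloride transporters, 2 passed, Gabra5 (277 ± 69.8 against 124 ± 56 CPM) and Gabrg1 (46.9 against 16.8 CPM), and 8 passed when adjusted over the list alone, each higher in up cells. The list was called higher (camera adjusted p = 0.0128), with adjusted p = 0.427 with an estimated correlation. Of 7 acetylcholine receptor subunits, 2 passed over all genes and over the list alone: Chrna3 (410 ± 155 against 211 ± 135 CPM, log2 1.06 ± 0.11) and Chrnb4 (34.2 against 9.61 CPM). That list had a camera adjusted p = 0.0418 and an adjusted p = 0.427 with an estimated correlation. Among channels, Cacna1i (1.35), Cacna1e (1.02) and Kcnc4 (1.15) were higher in up cells, and Kcnmb4 (−1.69), Kcnd3 (−0.68) and Cacng5 (−0.91) in down cells.

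Transcription factors and cell surface genes went both ways. Of 57 neural transcription factors, 4 were higher and 4 lower in up cells, and 6 and 18 when adjusted over the list alone. Onecut2 was higher in up cells (80.2 against 21 CPM, log2 1.54 ± 0.23), while Mef2c (log2 −1.50) and the LIM-homeodomain factor Isl1 (180 against 346 CPM, log2 −0.94 ± 0.10) were higher in down cells. This list was called lower in up cells (camera adjusted p = 0.00199, adjusted p = 0.427 with an estimated correlation). Of 16 general ganglion cell markers, 0 were higher and 3 lower in up cells (0 and 6 adjusted over the list alone), Isl1 and the neurofilaments Nefl (−0.54) and Nefm (−0.46), of which the last 2 had the opposite sign when log2 values were averaged over cells (0.0843 and 0.154). Camera called that list lower (adjusted p = 0.0472, and adjusted p = 0.427 with an estimated correlation), with a median log2 difference of −0.0244. Of 46 axon guidance genes, 2 were higher and 2 lower (10 and 6 adjusted over the list alone): the netrin receptor Dcc (1.07, adjusted p = 0.0484 in limma) and the Robo ligand Slit2 (0.70), against Efnb2 and Plxnc1 (−1.40). Of 29 cadherins, Cdh13 was higher in up cells (1.16) and 2 were lower. Of 60 immunoglobulin-type and related adhesion genes, 2 were higher and 7 lower, among them Igsf21 (−1.14) and Nrxn3 (−1.04). Galanin (Gal) had 2.51 CPM in up pools against 29.8 in down pools (log2 −1.99), and Igf1 2370 against 1460 CPM (log2 0.71). Of 28 nuclear genes of oxidative phosphorylation and 41 ribosomal protein genes, 0 passed in limma, with 1294 of all genes at an unadjusted p under 0.05.

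**Figure D2:**
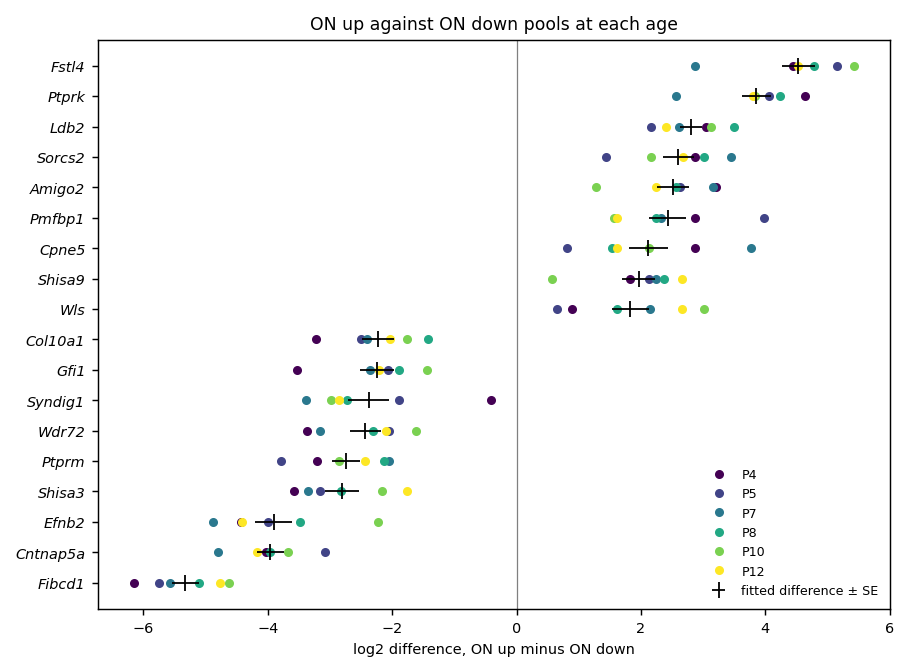
Log2 difference between ON cells labelled up and down for 18 genes, the 9 largest in each direction, with 1 dot per age from P4 to P12 and the fitted difference ± SE. The fitted values run from −5.33 for Fibcd1 to 4.53 for Fstl4, and each gene has the same sign at all 6 ages.

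Markers of other cells stood beside these differences. Of 10 glial genes, 0 passed in limma over all genes and 3 were lower in up cells when adjusted over the list alone, with a median log2 difference of −1.46 (camera adjusted p = 0.000779, adjusted p = 0.427 with an estimated correlation). The mean summed CPM of the glial list was 1067.9, 2116.0 and 1048.8 in down pools at P7, P8 and P10, which held 3, 3 and 2 cells of other types, and 273.3, 345.7 and 594.9 at P4, P5 and P12, against 267.3 to 780.8 in up pools. The horizontal cell list was also called lower in up cells (camera adjusted p = 0.0135, adjusted p = 0.387 with an estimated correlation). Of 11 direction-selective cell markers, Mmp17 was higher in up cells and Fam19a4 (−1.57) in down cells, and 1 and 6 when adjusted over the list alone (camera lower, adjusted p = 0.000779, and adjusted p = 0.238 with an estimated correlation). The list of early stress genes was called lower in up cells (camera adjusted p = 0.0145, adjusted p = 0.427 with an estimated correlation) with 0 of 11 genes past the limma threshold, and its direction turned in run 2 and without the cells of other types. Without those cells all 24 named genes passed. The test rests on 6 ages, and GFP itself marks Fstl4, so that gene's difference is set by the sort.

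Whether the difference between up and down changed with age was asked by a product term. In limma 0 of 11370 genes passed, with 385 at an unadjusted p under 0.05, and no list was called. In shuffled cells with known changes the same test recovered 18.5% of 4-fold changes, so changes of that size were mostly not detectable at this number of ages. Adjusted over the list alone, 2 of the candidate genes, 2 of the calcium-binding genes and 1 of the horizontal cell genes had a difference between up and down that became more positive with age, and 1 gene of immature neurons and 1 glutamate receptor gene one that became more negative. The first 3 of these lists share Calb1.

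The next comparison follows ON cells from P4 to P12, over which 16 of 22 measured genes of immature neurons fell and 11 of 25 synaptic vesicle genes rose. Cd24a, a surface protein of young neurons, changed by −3.98 ± 0.25 on the log2 scale over these days (SE, adjusted p = 8.66e-06, limma, 6 ages), Dcx, a microtubule protein of migrating and growing neurons, by −3.19 ± 0.23 (adjusted p = 1.94e-05), and St8sia2, which adds polysialic acid to NCAM, by −4.00 ± 0.43 (adjusted p = 0.00029). Lynx1, a brake on nicotinic acetylcholine receptors, rose by 4.59 ± 0.29 (adjusted p = 8.66e-06), the glycolytic enzyme Aldoc by 4.11 ± 0.27 (adjusted p = 8.66e-06) and the sodium channel subunit Scn2b by 2.997 ± 0.17 (adjusted p = 8.65e-06). The peptide gene Cartpt rose by 5.11 ± 0.57 (adjusted p = 0.000355).

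In limma 1232 of 11370 genes passed, 638 rising and 594 falling. Further named risers were Ramp1 (4.09), Mmp9 (4.07) and Mgarp (4.01), and further named fallers Tes (−3.90), Fxyd6 (−3.64), Ecel1 (−3.60), AW551984 (−3.38), Grm3 (−3.37), B3gnt5 (−3.30) and Fblim1 (−3.22). The 20 named genes had the same sign in each run, and 601 and 614 genes passed within the runs. Of 22 genes of immature neurons 1 rose and 16 fell (1 and 18 adjusted over the list alone), with Stmn1 at −1.73 ± 0.18 and Sox11 at −1.88 ± 0.42 (camera adjusted p = 1.35e-09, adjusted p = 0.23 with an estimated correlation). Of 25 synaptic vesicle genes 11 rose (16 rose and 1 fell adjusted over the list alone), among them Syt2 (2.68), Vamp1 (2.28) and Cplx1 (1.55), with camera adjusted p = 1.35e-06 and adjusted p = 0.229 with an estimated correlation. Of 7 acetylcholine receptor genes 3 rose (5 adjusted over the list alone): Chrna6 (2.65 ± 0.22), Chrna3 (1.75 ± 0.17) and Chrnb3 (1.43 ± 0.21). Camera gave adjusted p = 0.000567 for them and adjusted p = 0.229 with an estimated correlation.

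Ion channels shifted in both directions. Of 10 sodium channel genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Scn3b and Scn9a at −1.19 and −1.13 (camera adjusted p = 0.0484, adjusted p = 0.312 with an estimated correlation). Of 38 potassium channel genes 9 rose and 2 fell (12 and 3 adjusted over the list alone), with Kcnip4 at 3.12, Kcna1 at 2.73 and Kcnip2 at 2.42 (camera adjusted p = 0.00869, adjusted p = 0.229 with an estimated correlation). Grin2a, an NMDA receptor subunit, rose by 3.11 ± 0.26, and the chloride transporter Slc12a5 by 1.11 ± 0.18. Of 46 axon guidance genes 1 rose, Sema5a (2.46), and 6 fell, among them Plxna3 (−1.92), against 1 and 7 adjusted over the list alone (camera lower, adjusted p = 0.0303, and adjusted p = 0.312 with an estimated correlation).

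Metabolic and ribosomal lists were also tested. Of 41 ribosomal protein genes 23 fell (38 adjusted over the list alone), including Rps19 (−1.57) and Rpl13 (−1.31), with camera adjusted p = 5.21e-14 and adjusted p = 0.312 with an estimated correlation. Ribosomal protein genes have many processed copies that share reads with them, so single values are uncertain. Of 28 nuclear oxidative phosphorylation genes 10 rose (12 adjusted over the list alone), including Uqcrc1 (0.99), with camera adjusted p = 5.48e-07 and adjusted p = 0.312 with an estimated correlation. Of 19 genes of cholesterol synthesis 7 fell (10 fell and 1 rose adjusted over the list alone), including Fdps (−1.39) and Lss (−1.23), with camera adjusted p = 0.000287, adjusted p = 0.464 with an estimated correlation and adjusted p = 0.116 in fry.

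**Figure D3:**
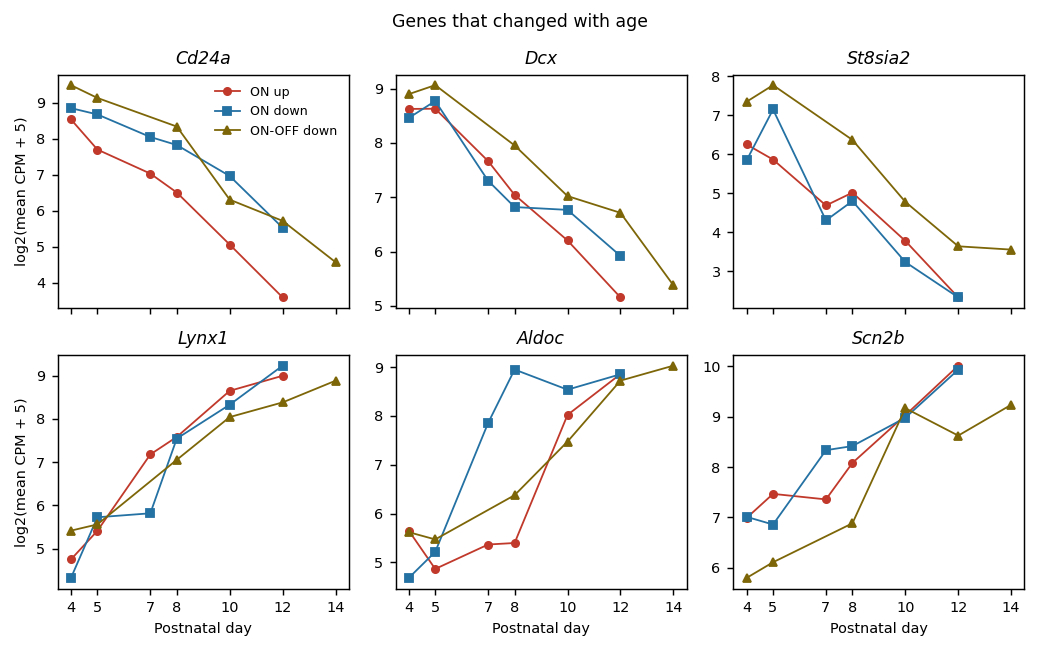
Mean expression of 6 genes, as log2(mean CPM + 5), against postnatal day, with 1 point per pool for ON up, ON down and ON-OFF down cells. In ON cells Cd24a, Dcx and St8sia2 changed by −3.98, −3.19 and −4.00 from P4 to P12, and Lynx1, Aldoc and Scn2b rose by 4.59, 4.11 and 2.997.

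Transcripts of rod photoreceptors rose in the same pools. Sag rose by 5.27 ± 1.08 (adjusted p = 0.0249, limma), Pde6b by 3.97 ± 0.45 (adjusted p = 0.00039) and Pdc by 4.11 ± 1.02 (adjusted p = 0.0458). Of 12 rod genes 10 rose and 12 when adjusted over the list alone (camera adjusted p = 3.44e-11, adjusted p = 0.312 with an estimated correlation). From P4 to P12 the mean summed CPM of the rod list was 6.8, 20.8, 226.2, 802.5, 130.6 and 1429.9 in up pools, an uneven rise, and 494.9 in the down pool at P12. Of 10 glial genes 2 rose, Clu (1.51) and Glul, and the camera adjusted p = 0.0114 became adjusted p = 0.501 with an estimated correlation. Camera also called 3 more lists of other types or quality higher with age: early stress genes (2 of 11 rose, adjusted p = 0.0325, and 0.464 with an estimated correlation), horizontal cell genes (2 of 5 rose, 0.0217 and 0.312) and bipolar cell genes (0.0462 and 0.587). The fitted trend is linear over 6 ages, and without P12, P4, P10 or P5 the count of genes was 388, 620, 796 or 802.

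ON-OFF cells were compared with ON cells of the same 5 ages. Calb2 (calretinin, ENSMUSG00000003657.9, chromosome 8, 110137502 to 110168210, minus strand) had 2300 ± 657 CPM in ON-OFF pools, against 23.8 ± 26.9 in up pools and 309 ± 309 in down pools (SD, n = 5 ages). The copine Cpne4 had 341 ± 63.6 against 2.28 ± 3.19 and 43.7 ± 42.5 CPM, the protocadherin Pcdh11x 386 ± 81.5 against 3.83 ± 4.17 and 36 ± 20.4 CPM, and the AP-2 factor Tfap2d 141 ± 45.7 against 0.00606 ± 0.0135 and 6.85 ± 10.8 CPM. Higher in ON cells were the growth factor Igf1 (ENSMUSG00000020053.18, chromosome 10, 87858265 to 87937042, plus strand), with 2390 ± 374 CPM in up and 1450 ± 338 in down pools against 113 ± 34.9 in ON-OFF pools, and the membrane metalloproteinase Mmp17, with 266 ± 65.4 and 75.0 ± 9.31 against 6.82 ± 3.45 CPM.

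In limma 1103 of 11427 genes passed, 531 higher and 572 lower in ON-OFF cells, and 1035 had the same sign at all 5 ages. Calb2 differed by 5.14 ± 0.23 (adjusted p = 1.12e-07), Cpne4 by 4.66 ± 0.30 (adjusted p = 1.15e-06), Pcdh11x by 4.55 ± 0.23 (adjusted p = 1.81e-07), Igf1 by −4.00 ± 0.15 (adjusted p = 2.25e-08) and Mmp17 by −3.66 ± 0.19 (adjusted p = 2.63e-07). Other named genes above were Cartpt (4.42), Tfap2d (4.36), Hmgn2 (3.99), Tusc5 (3.92), Tac1 (3.65), Kctd12 (3.62) and Ctss (3.91), a gene of the microglial list. Below were Eno1b (−4.59), Syt6 (−3.47), Pappa (−3.13), Igfbp7 (−3.13), Dab1 (−3.06), Mmp12 (−2.99), Whrn (−2.96) and Crabp1 (−2.95). Hmgn2 and Eno1b have near-identical copies elsewhere in the genome, so their values are uncertain. The 20 named genes had the same sign in each run, with 573 and 545 genes past the threshold within the runs and 710 without P8.

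Of 64 neural transcription factors 26 were higher and 8 lower in ON-OFF cells (33 and 12 adjusted over the list alone): Satb1 (log2 3.56 ± 0.27), Isl2 (3.06 ± 0.16) and Foxp1, with 88.6 CPM against 4.13 and 11.2 in up and down pools, lay among the higher ones. Camera gave adjusted p = 2.5e-07, and adjusted p = 0.247 with an estimated correlation. The POU factors Pou4f1 (1120 ± 398 CPM against 121 ± 28.1 and 219 ± 113) and Pou4f3 (88.8 ± 29.1 against 0 and 39.6 CPM) were also higher. Of 22 genes of immature neurons 9 were higher (12 adjusted over the list alone), including Sox11 (2.099 ± 0.14), Sox4 (1.31) and Stmn1 (1.08), with camera adjusted p = 2.56e-06 and adjusted p = 0.329 with an estimated correlation. Of 13 direction-selective cell markers 8 were higher and 4 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.000968, adjusted p = 0.329 with an estimated correlation).

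Surface and channel genes went both ways. Of 31 cadherins 6 were higher, among them Cdh4 (3.44) and Cdh10 (3.25), and 11 lower, among them Pcdh9 (1190 ± 124 and 901 ± 274 CPM in up and down pools against 168 ± 67.4), against 7 and 12 adjusted over the list alone. Of 47 axon guidance genes 9 were higher, including Sema3e (2.25), and 9 lower, including Robo1 (−2.59) and Plxnd1 (−2.46), against 12 and 13 over the list alone. Of 62 immunoglobulin-type adhesion genes 12 were higher and 13 lower, with Adgrl2 at 2.96 and Kirrel3 at −1.84. Of 10 sodium channel genes 3 were lower. The receptor subunits Gabra5 (−1.66) and Gabra2 (−0.99), and Slc12a5 (−1.18) were lower in ON-OFF cells, and the NMDA receptor subunit Grin3a (3.40) higher. Fstl4 was 1.499 ± 0.19 higher against the average of up and down, which the sort by its reporter sets in part, and −0.468 when log2 values were averaged over cells.

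**Figure D4:**
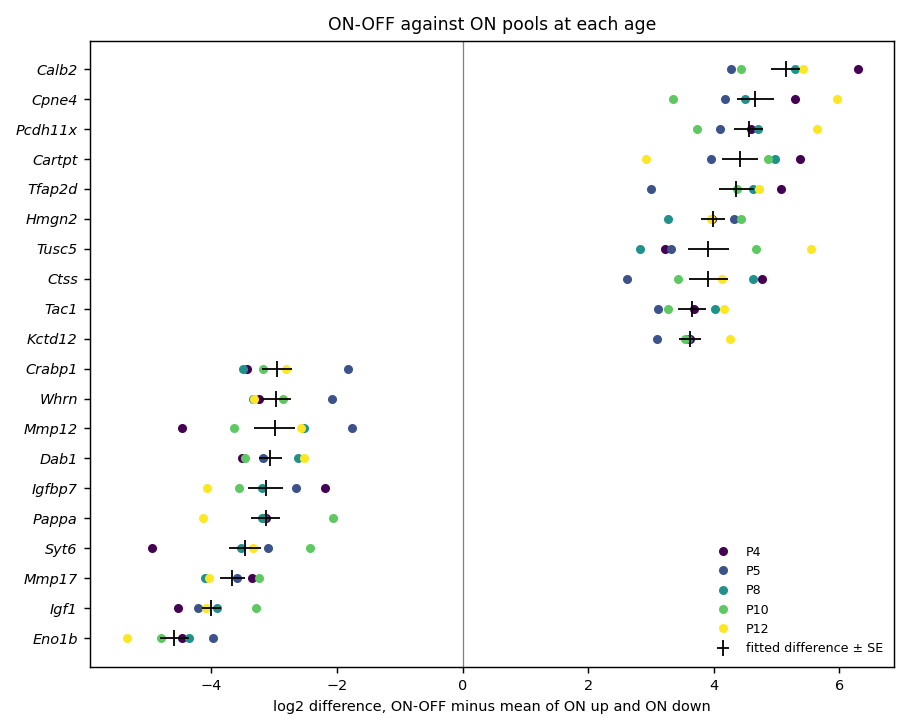
Log2 difference between ON-OFF cells labelled down and the mean of ON up and ON down cells for 20 genes, with 1 dot per shared age and the fitted difference ± SE. The fitted values run from −4.59 for Eno1b to 5.14 for Calb2, and each gene has the same sign at all 5 ages.

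Microglial transcripts moved with the ON-OFF group although the sort excluded CD11b-positive cells. All 10 measured microglial genes were higher, over all genes and over the list alone, including C1qb (57.4 CPM against 0.23 and 0.102), C1qc (38.7 against 0 and 0) and C1qa (29.2 against 0.0262 and 0.33), with camera adjusted p = 6.01e-12 and adjusted p = 0.329 with an estimated correlation. In the fit of ON pools alone, 2 of the 12 listed genes reached the expression filter. The others entered here through the ON-OFF pools and could hardly come out lower. Of 192 ON-OFF cells, 10 held 99% of the C1q, Ctss and Tyrobp signal, so the genes are not separate pieces of support. The mean summed CPM of that list was 145.9 to 712.1 in the ON-OFF pools of the 5 shared ages, 16.8 to 54.3 in up pools and 16 to 50.9 in down pools of those ages, and 255.6 in the down pool at P7, outside this comparison. The glial gene Apoe was higher (2.24) and Clu lower (−1.09). Horizontal cell genes (2 of 4 lower) and rod genes were called lower in ON-OFF cells (camera adjusted p = 0.00399 and 0.0179, and 0.464 and 0.759 with an estimated correlation), as were nuclear oxidative phosphorylation genes (3 of 28 lower and 1 higher, 0.00717 and 0.608). Sex differed between the pools: at P5 and P12, 0 ON cells had transcripts of the Y chromosome without Xist, while in ON-OFF pools 31 of 38 and 21 of 29 cells did, a check chosen after the values were seen. ON-OFF and ON cells come from different mouse lines, so type and line cannot be told apart.

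Restricting the comparison to cells labelled down matched the labelled preferred direction. These fits share the ON-OFF pools with the previous ones, so their results are not independent. The ON down pools were not uniform, so only the label is matched. Fibcd1 had a fragment in 57.5% to 95.7% of ON down cells per pool, and 12 of 32 at P10 had neither Fstl4 nor Fibcd1. In limma 789 of 11500 genes passed, 387 higher and 402 lower in ON-OFF cells, and 738 had the same sign at all 5 ages. Fstl4 had 156 ± 54.4 CPM in ON-OFF down pools against 5.25 ± 1.89 in ON down pools, a log2 difference of 3.93 ± 0.26 that is set in part by the sort, since ON down cells were taken for the lack of GFP that marks Fstl4. Fibcd1 had 15.6 against 237 CPM, a difference of −3.91 ± 0.39 (adjusted p = 0.000243). Hmgn2 (4.00), the microglial list gene Ctss (3.91), Tfap2d (3.91) and Cartpt (3.84) were higher, and Eno1b (−4.76), Igf1 (−3.63), Igfbp7 (−3.56) and Syt6 (−3.46) lower. Of 64 neural transcription factors 20 were higher and 6 lower (26 and 12 adjusted over the list alone, camera adjusted p = 0.000917, adjusted p = 0.402 with an estimated correlation). Of 23 genes of immature neurons 7 were higher (13 over the list alone, camera adjusted p = 1.47e-06, adjusted p = 0.402 with an estimated correlation), and of 10 microglial genes 9 (10 over the list alone, camera adjusted p = 3.27e-13, adjusted p = 0.402 with an estimated correlation). The limits given above for the microglial list hold here too. Lower in ON-OFF cells by camera were horizontal cell genes (adjusted p = 0.00104, and 0.402 with an estimated correlation), glial genes (0.0248 and 0.697), rod genes (0.0372 and 0.847) and nuclear oxidative phosphorylation genes (0.0112 and 0.697). Within the runs 378 and 395 genes passed, and the 10 named genes had the same sign in each. Without P4 or P8 the count was 441 or 498.

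In ON-OFF cells from P4 to P14 the same broad groups were followed. Cd24a changed by −5.04 ± 0.36 (adjusted p = 6.42e-05, limma, 6 ages), St8sia2 by −4.58 ± 0.46 (adjusted p = 0.000284) and Dcx by −3.53 ± 0.31 (adjusted p = 0.000149). Mgarp rose by 4.48 ± 0.36 (adjusted p = 0.000124), Aldoc by 3.84 ± 0.34 (adjusted p = 0.000149), Lynx1 by 3.71 ± 0.31 (adjusted p = 0.000124) and Scn2b by 3.72 ± 0.47 (adjusted p = 0.00131). Further risers were Rasgrf1 (4.44), the myelin-associated protein Omg (4.30), Tusc5 (3.95), Fstl1 (3.92), Fgf1 (3.90) and Cartpt (3.80), and further fallers Fblim1 (−4.17), B3gnt5 (−3.95), Fxyd6 (−3.91), Ypel1 (−3.64), Mex3a (−3.51), Vash2 (−3.38) and Fnbp1l (−3.30). In limma 436 of 11458 genes passed, 219 rising and 217 falling, and 115 and 228 within the runs.

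Of 23 genes of immature neurons 1 rose and 13 fell (1 and 15 adjusted over the list alone), including Sox11 (−3.06 ± 0.44), with camera adjusted p = 5.78e-09 and adjusted p = 0.28 with an estimated correlation. Of 25 synaptic vesicle genes 8 rose and 2 fell (15 and 2 over the list alone), including Vamp1 (2.74) and Sv2c (2.18), with camera adjusted p = 1.74e-05 and adjusted p = 0.28 with an estimated correlation. Of 19 cholesterol synthesis genes 5 fell (10 over the list alone), including Mvd (−2.09) and Lss (−1.87), with camera adjusted p = 1.82e-05 and adjusted p = 0.28 with an estimated correlation. Of 20 genes of GABA and glycine receptors, their anchor and chloride transporters, 3 rose (4 over the list alone), including the transporter Slc12a5 (2.24) and the receptor subunit Glrb (1.67), with camera adjusted p = 0.00176 and adjusted p = 0.28 with an estimated correlation. Kcna2 (2.37) rose among 37 potassium channel genes. Of 7 rod genes 1 rose, and 2 over the list alone. Camera also called microglial genes (adjusted p = 0.00309, and 0.514 with an estimated correlation) and mitochondrially encoded genes (0.0291 and 0.514) higher with age and ribosomal protein genes lower (1 of 41 fell, 0.000478 and 0.604). Without P4, P5 or P8 the count of genes was 88, 116 or 275, and without P14 it was 708.

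Among 10803 genes tested in both trends, 171 rose in both, against 12 for independent lists of 604 and 214 genes, and 152 fell in both, against 11.2 for lists of 580 and 209. A single gene went opposite ways. Of the ON-OFF risers 98.1% had a positive slope in ON cells, and of the fallers 96.7% a negative one. The test of the difference in slope called 0 of 11427 genes in limma, with 1505 at an unadjusted p under 0.05, so a gene called in one group and not in the other is not shown to differ. Averaging log2 values over cells called 1184 genes instead, 28 higher and 1156 lower. From P4 to P12 the median of detected genes per cell went from 7849 to 5738 in ON-OFF pools. It went from 7393 to 8022 in up pools and from 8732 to 7854 in down pools. A mean of log2 values falls where genes go undetected, so these calls cannot be told apart from a change in detection. Camera called the rod list lower in slope in ON-OFF cells (adjusted p = 7e-08, 10 of 12 genes adjusted over the list alone), with adjusted p = 0.784 with an estimated correlation and 0.506 in fry, and no rod gene passed over all genes. It also called early stress genes (0.0152) and acetylcholine receptor genes (0.0411) lower, each with adjusted p = 0.784 with an estimated correlation.

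The Pcdh9-Cre ON cells at P10 form a single pool with no replicate, so the values are described without a test. Fstl4 had 296 CPM, against 315 in the up pool, 2.45 in the down pool and 218 in the ON-OFF pool of that age, and a fragment in 57 of 92 cells (62%, exact 95% interval 51.2 to 71.9). Fibcd1 had 2.65 CPM (1.83 up, 163 down, 23.2 ON-OFF). Tfap2b had 91.7 CPM (0.0735 up, 3.16 down, 0 ON-OFF), Tbx5 4.77 (12.2, 3.34 and 1.94), Sfrp1 19 (41, 8.5 and 11.2), Pcdh11x 70.9 (9.08, 51.6 and 371) and Calb1 245 (696, 454 and 89). The gate gene Pcdh9 had 488 CPM, against 1020, 819 and 247. Mnx1 had a fragment in 0 of 92 cells, which allows a share of up to 3.26%, and in 35 of 49 ON-OFF cells (71.4%, 56.7 to 83.4).

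The transcripts with the largest excess in the Pcdh9-Cre pool were microglial or immune genes. Ctss had 986 CPM and a fragment in 39 of 92 cells (42.4%, 32.1 to 53.1), with 0 of 45 up cells, which allows a share of up to 6.67%, and 0 of 32 down cells, which allows up to 9.38%. Selenop (703 CPM), Lyz2 (649), C1qb (564), C1qa (443), C1qc (429), B2m (412), Tyrobp (290), Fcgr3 (209) and Cx3cr1 (208) followed. Among the lowest against the mean of the up and down pools were Fibcd1, Eif2s3y (0 CPM) and Ddx3y (0.0176), which lie on the Y chromosome, Mmp9 (19.1 against 155), Scn2b (76.2 against 509), Olfm4 (24.1 against 125), Wdr72 (3.01 against 30.5) and Dusp3 (209 against 910). The mean summed CPM was 4511.4 for the microglial list, 5817.9 for the rod list and 2991.0 for the glial list, and in 36 of the 92 cells a list of another type exceeded the ganglion cell list. Without those cells Tfap2b had 31.6 CPM, Ctss 42.6, Fstl4 449, Pcdh11x 108, Tbx5 7.19, Sfrp1 25.7, Calb1 306 and Pcdh9 720. The transcript CT010467.1 took 15.9% of the Pcdh9-Cre pool, against 5.27% in the up, 4.99% in the down and 3.57% in the ON-OFF pool at P10. It is part of the total behind each CPM, so it lowers the CPM of all other genes there. All 92 libraries were sequenced in run 2, as were 22 of the 45 up cells, 16 of the 32 down cells and 24 of the 49 ON-OFF cells at P10, and the comparison was not repeated within run 2.

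**Figure D5:**
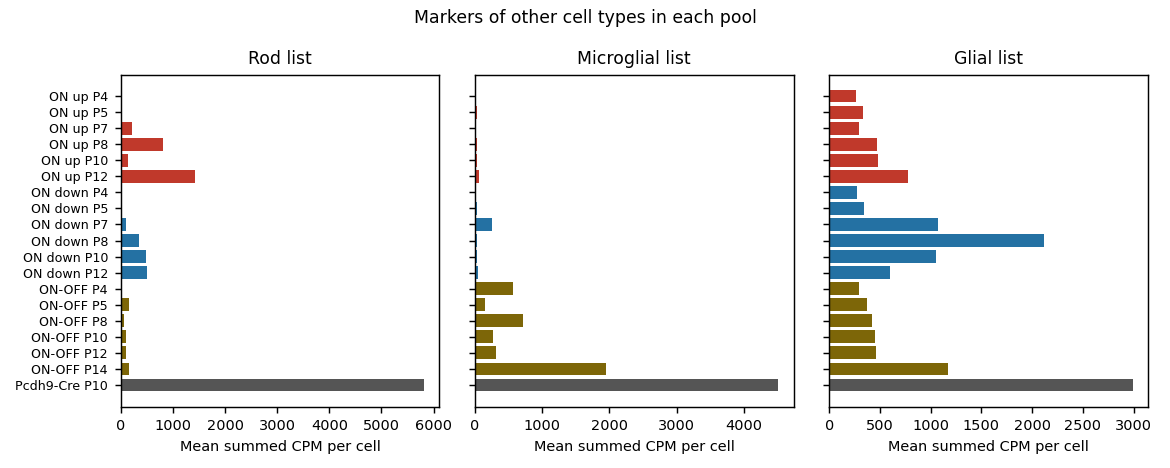
Mean summed CPM per cell of the rod, microglial and glial lists (bars, from 0) in each of the 19 pools. The Pcdh9-Cre pool stands at 5817.9, 4511.4 and 2991.0, and the rod list in ON up pools goes from 6.8 at P4 to 1429.9 at P12, with 802.5 at P8 and 130.6 at P10.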

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

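All tests in this part were chosen after the result was seen, except the test of barcode spill within sequencing run 1. The counts over other orders or swaps of labels test each comparison named below.

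The spread of 107 groups of 5 or 6 pools or ages was searched for 1 value far from the rest. There were 10 such values, where chance gives about 1 in 20 groups, or 5.3. In ON-OFF down against ON down cells, the log2 difference of Hmgn2 was 3.10 at P8 against 4.06 to 4.43 at the other ages. That of Tfap2d was 1.68 at P5 against 4.16 to 4.67. That of Igfbp7 was −4.38 at P12 against −3.53 to −3.21, and that of Pcdh11x was 6.09 at P12 against 2.73 to 3.19. The mean summed CPM of the cone list was 462 in the ON down pool at P10 against 7.3 to 158 at the other ages. The glial list stood at 1170 in the ON-OFF pool at P14 against 289 to 461. The microglial list stood at 256 in the ON down pool at P7 against 16 to 50.9, and at 1950 in the ON-OFF pool at P14 against 146 to 712. The vascular list stood at 81.4 in the ON up pool at P12 against 16.9 to 28.4. The erythroid list stood at 420 in the ON down pool at P7 against 0.8 to 19.7.

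The summed signal of microglial genes was higher in each ON-OFF pool of the shared ages than in the ON pools of those ages, although CD11b-positive cells were excluded from the sort, and 2 of the 12 listed genes reached the expression filter in ON pools. Free microglial RNA spread over all HB9-GFP cells was excluded: a C1q fragment was found in 18 of 192 cells at the shared ages (9.38%, exact interval 5.7 to 14.4), and in 8 of 390 ON cells (2.05%, 0.9 to 4.0). The 10 of these 192 cells with the most signal (5%) held 99% of the summed C1qa, C1qb, C1qc, Ctss and Tyrobp signal. This is consistent with a few cells that are microglia, or that carry microglial material, passing the sort. In ON-OFF pools at P5, P10 and P12, 0 cells had a list of another type above the ganglion cell list, against 1 each at P4 and P8. The microglial list still stood at 145.9, 268.8 and 307.3 CPM at P5, P10 and P12. This argues against microglia sorted alone as the cause at these 3 ages. Ganglion cells with attached fragments, or sorted together with a microglial cell, stay open, and no biological explanation was tested.

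Rod genes rose with age in ON pools. Barcode spill from the rod-rich Pcdh9-Cre libraries of run 2 was excluded as the whole cause, if the runs are as read from the index numbers. The median rod log2 change was 2.63 in run 1 alone and 3.33 in run 2. Cells with more rod than ganglion cell transcripts were excluded as the whole cause. Without the cells of other types 11 rod genes rose, with a median change of 3.16. At P12 this filter set aside 1 cell in the up pool and 0 in the down pool. It would keep a rod sorted together with a ganglion cell, so that case is not excluded. Free rod RNA spread evenly over a pool was excluded, since the 90th percentile over the median of summed rod CPM at P12 was 27.9 in the down pool and 47.7 in the up pool, with 6 and 7 cells lacking any rod fragment. Uneven rod debris on single cells and transcription in ganglion cells stay open and were not tested, and age is a difference that the design names.

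Transcripts of Gm13394, Eno1b and Gm15487 were near absent from each HB9-GFP pool and present in nearly every ON cell (log2 −4.37, −4.59 and −2.68). A median of 97.2% of the 36 Pcdh9-Cre cells of other types had a fragment of them. Cells set aside could also hold ganglion cell transcripts. In the Pcdh9-Cre pool 56 of 92 cells were not set aside. Of the 92, Nefl had a fragment in 81, Igf1 in 76, Rbpms in 65 and Slc17a6 in 64. Rbpms had 371 CPM there, against a mean of 724 in the ON pools at P10. Gm13394, Eno1b and Gm15487 had 282, 151 and 57.5 CPM, against 75.1 to 177, 76.1 to 252 and 34.2 to 56.6 over ON pools. Of 9 Spig1-GFP cells of other types, a median of 88.9% had a fragment. These values argue against expression confined to ON ganglion cells, but do not exclude it. A strain variant that separates the HB9-GFP line from the others cannot be told apart from other causes, because only 4 HB9-GFP cells of other types were found, of which a median of 50% had a fragment (exact interval 6.8 to 93.2), with Gm15487 in all 4. The median over the other HB9-GFP cells was 47.6%. Gm13394 and Gm15487 are annotated as processed pseudogenes, so reads shared with their parent genes stay open. Line and cell type are confounded in the design.

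Other arrangements of the same pools were fitted to ask whether chance could give as many genes. For up against down, 1 of 32 swaps of labels within ages, the real one, gave as many as the 191 genes. The highest of the others gave 1 gene. This share of 0.0312 is the lowest that 32 swaps can give, and it concerns the count as a whole, not single genes. Swapped labels leave the real differences in the residuals, which lowers the counts of the other swaps. For the age trend in ON cells, 1 of 100 orders of the ages, the real one, gave as many as the 1232 genes, a share of 0.01. The highest of the others gave 251. For the age trend in ON-OFF cells, 4 of 100 orders, the real one among them, gave as many as the 436 genes, a share of 0.04. The 100 orders are a sample of all possible ones, so a share this near 0.05 does not exclude chance. The order with the highest count, 929 genes, has P12 and P14 exchanged and differs from the real order only in these last 2 ages. It lies above the real count. The ON-OFF pool at P14 also differed from that at P12 in median detected genes (8608 against 5738) and in the share of CT010467.1 (7.52% against 3.55%). Whether a trend that is not linear in days or such differences between pools gave the higher count was not tested. For ON-OFF against ON, 1 of 16 swaps gave as many as the 1103 genes, with 0 the highest of the others, and for ON-OFF down against ON down, 1 of 16 gave as many as the 789 genes, with 1 the highest of the others. These 16 swaps are too few for a share under 0.05. For the product terms the real count was 0 genes, which 100 of 100 orders reach by necessity (3 the highest for up against down and 8 for type), so this count says nothing about chance.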

How the results depend on the processing

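Tests within each sequencing run, and gene set tests without cells of other types, were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible by replicate number, because these numbers in the labels only number single cells within a group, and the age block pairs pools by age. The planned count models were not run, since raw counts were not recovered. Other planned settings not named here left the counts within 1.5 times. For up against down (191 genes) no filter gave 12, FPKM 99, thinned pools 116, plain empirical Bayes 112, no age block 94, run 1 117 and run 2 70, and leaving out an age gave 129 to 145. For the ON age trend (1232) no filter gave 0 in limma (3596 at an unadjusted p under 0.05), plain empirical Bayes 762, run 1 601 and run 2 614. Leaving out an age gave 388 (without P12) to 1266 (without P7), with 620 without P4, 802 without P5 and 796 without P10. For ON-OFF against ON (1103) no filter gave 265, no age block 614, run 1 573 and run 2 545, and leaving out an age 710 (without P8) to 998. For ON-OFF down against ON down (789) no filter gave 16, no block 450, run 1 378 and run 2 395, and leaving out an age 441 (without P4) to 643, with 498 without P8. For the ON-OFF age trend (436) no filter gave 0 (2627 unadjusted), FPKM 184, plain empirical Bayes 143, run 1 115 and run 2 228, and leaving out an age 88 (without P4) to 708 (without P14), with 116 without P5 and 275 without P8. For type by age (0) a pseudocount of 1 gave 1, a filter of 20 CPM 56, sums over cells 3, the mean of log2 values 1184, 3000 detected genes 1, thinned pools 4, and leaving out an age 0 to 3 (without P12). Up against down by age stayed at 0 in all settings. Without a filter the prior degrees of freedom fell, from 7.5 to 1.25 for up against down. Fits within runs and without an age hold fewer cells or ages. For the other settings the cause was not tested. Beside 56 gene set calls, an estimated correlation gave 0, fry 31 (25 of them among the 56), pools without cells of other types 47 (46), run 1 46 (43) and run 2 53 (44). The mean of log2 values reversed Nefl (0.0843) and Nefm (0.154) in up against down, Fstl4 (−0.468) in ON-OFF against ON and Caln1 (−0.154) in ON-OFF down against ON down. Among single genes, taken after the fits as the largest changes or from the gene lists, with the direction as before, 354 no longer passed without a filter, 143 in each run, 133 with FPKM, 119 with plain empirical Bayes, 84 without an age block, 73 with the mean of log2 values, 73 with thinned pools, 20 with sums over cells and 13 to 137 without an age. The other settings gave 18 or fewer. The mean of log2 values brought 58 past the threshold, the most of any setting. Sets that turned were early stress genes in up against down (adjusted p = 0.428 without cells of other types, 0.56 in run 2), rod genes in up against down by age (0.00831 in run 1) and microglial genes in type by age (0.0256 in run 1). The mean of log2 values moved the share of higher calls from 58.6% to 71.8% in up against down, from 48.1% to 20% and from 49% to 20.6% in the ON-OFF comparisons, where the median of all genes was −0.316 and −0.314 against −0.00787 and −0.00551, and from 50.2% to 31.5% in the ON-OFF trend. Median-of-ratios scaling gave 64.4% there, and FPKM 63% there and 66.1% against 51.8% in the ON trend. Fstl4 in Pcdh9-Cre cells was 296 CPM from summed counts and 449 without cells of other types. Depth limits the detection of low genes per cell.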

Other observations

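The test of the Pcdh9-Cre cells in this part was chosen after the result was seen, and the genes in the next paragraph were picked after their values were seen.

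Cells labelled down by the lack of GFP were not uniform. Pou4f3, a POU factor of some ganglion cell types, was listed at 0 in each up pool and stood at 23.5, 110, 0, 12.7, 50 and 2.13 CPM in down pools from P4 to P12. Eomes, a T-box factor of intrinsically photosensitive ganglion cells, had a fragment in 10%, 16.1% and 15.6% of down cells at P5, P8 and P10, and Tbx20 in 2.5%, 16.1% and 18.8%. At P4, P7 and P12 both were listed at 0 in down pools. Calb2 followed the same pools, with 529, 186 and 736 CPM at P5, P8 and P10 against 36.4, 0 and 59.2 CPM at P4, P7 and P12. Fibcd1, by contrast, was found in 95.7%, 83.3% and 90% of down cells at P4, P7 and P12 and in 57.5%, 67.7% and 59.4% at P5, P8 and P10. At P10, 14 of 32 down cells had Fibcd1 without Fstl4, 1 had Fstl4 alone, 5 had both and 12 had neither. No test was run on these shares, since each is from 1 pool.

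Sex-linked transcripts separated the pools by age and line. In ON pools at P5, 39 of 41 up cells and 39 of 40 down cells had Xist without a Y transcript, and at P12 43 of 43 and 40 of 40. In ON-OFF pools at P5, P10, P12 and P14, 31, 42, 21 and 43 cells had a Y transcript without Xist and 0, 0, 1 and 0 the reverse, while P4 and P8 were mixed (20 and 18 cells with Xist alone, 18 and 17 with Y alone). Of 92 Pcdh9-Cre cells 90 had Xist alone.

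A hypothesis for the Pcdh9-Cre cells is that most of the ganglion cells among them are of the type labelled up. Of these 92 cells, 43 had Fstl4 without Fibcd1 (46.7%, exact interval 36.3 to 57.4), 4 had Fibcd1 alone (4.35%, 1.2 to 10.8), 14 both and 31 neither. Without the 36 cells of other types the shares were 66.1% (37 of 56, 52.2 to 78.2), 5.36%, 19.6% and 8.93%. Of 135 genes called between up and down without P10, 90 (66.7%) lay nearer to the up pool than to the down pool once cells of other types were left out, and 62 (45.9%) with all cells. Among these genes 45 of 75 higher in up cells and 45 of 60 higher in down cells were nearer to up. A mixture of types could give the same values, the ON-OFF pool at P10 also had 30 of 49 cells with Fstl4 alone (61.2%), and the line differs from the other pools, so the hypothesis stays open.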
